A study of Mus musculus with 12 samples.

How the data were processed

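Genomic DNA of mouse DN2/DN3 T cell precursors was examined by LAM-HTGTS, a linear amplification method that reads outward from a fixed bait sequence and records the genomic position to which the bait end has been joined. Per the labels' protocols, precursors were kept for 14 days on OP9-DL1 stroma, a bone marrow stromal line carrying a Notch ligand, with Flt3-L and IL-7 at 5 ng/ml each. CD140a-positive stroma and B220-positive B cells were then removed with antibodies, and the DNA was broken by sonication and read on a MiSeq. The bait was the Trdd2 diversity segment, read from its 5′ side (5P) or its 3′ side (3P), in wild type (WT) cells or in cells with a knocked-in CTCF binding element (CBE KI). Each of the 4 groups held 3 libraries. Groups were taken from the sample titles. The genotype tag of the CBE KI libraries names another allele, so the genotype rests on the titles alone. The labels do not say that replicates came from separate cultures or animals, so the p-values measure the spread between these libraries, which may be technical.

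Per the file headers, the authors deposited 1 line per sequence read, with the genomic position and strand of the bait and of the joined partner and the read sequence. These values are genome positions and strands, not counts, so junctions were counted from the lines. Positions are in mm9, per the submitters' processing notes. The aligner, its version, the filters and any removal of duplicate reads are not given in the sources used here. The file of 3P WT replicate 1 carries additional filter columns in its header, among them a mapping flag that is 0 on each line. Lines that repeat the same positions were present in every library, and collapsing lines with the same chromosome, junction position, strand, partner end and bait end left 17.3% to 36.0% of them. No molecular identifiers were used here and PCR reads are not independent molecules, so intervals and floors cover counting error only. Read names place the libraries on 5 sequencing runs. All 6 CBE KI libraries shared 1 run, and the WT libraries were spread over 4 other runs, so no run held both genotypes. WT replicates 2 of both baits shared a run, as did WT replicates 3.

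No mm9 genome or annotation was used here. Segments were therefore placed from the read sequences. Over all 12 libraries pooled, positions with at least 8 junctions within 3 bp of a peak and at least 20 within 50 bp were called as sites, and the consensus sequence on either side was read for a recombination heptamer and for the coding end of a V, D or J segment. Of 184 sites, 68 were segments (34 V, 33 J and 1 D), and 43 of these were named. Trdv1 and Trdv2-1 took their names from the order of neighbouring segments, the others from their coding ends. The order of 39 names could be compared with a RefSeq gene table of GRCm38.p6, which was used for names and order only, and all 39 kept it. For Trdv1 and Trdv2-1 this was fixed by the way they were named. The remaining V sites are given by position. Near-identical copies of the Trav15-dv6 family share reads, so their placement is uncertain. Trdv3 was not settled, and Trdc was not placed, so the border of the region upstream of Trdv5 was set at Trdj2. The planned list of Trav segments became the list of V sites without a settled name.

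A junction was assigned to a segment within 50 bp of its border with the recombination signal. The denominator was all junctions in the locus (chromosome 14, 53220688 to 54686122, which is 50000 bp beyond the outermost sites) further than 200 bp from Trdd2. Shares are percentages of that denominator, or of off-segment junctions where stated, and those of Trb and Trg are percentages of all deposited junctions of a library. Fits across segments used limma-voom (limma 3.58.1 in R 4.3.3, statmod 1.5.0), two-sided with Benjamini-Hochberg adjustment, on segments with at least 10 junctions over the libraries in the fit, and the denominator as library size. Each bait was fitted on its own, and the interaction of bait and genotype was fitted over all 12 libraries on segments with at least 10 junctions in the libraries of each bait. Off-segment junctions were counted in 10 kb bins and fitted in the same way. Single shares were compared by two-sided exact permutation tests, in which 3 libraries against 3 cannot give a p below 0.10. For Trdv5, labels were also permuted within each bait (400 arrangements, smallest p 0.005). A fold against a group without junctions was computed against 3 counts over the group and is a lower bound. Where a group had 1 to 3 junctions, the ratio of pooled shares is given with its 95% counting interval. Counting used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and Biopython 1.88, and figures used matplotlib 3.10.9.

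The rule for named segments was fixed before the data were examined. It takes, per bait, each Trdv, Trdd and Trdj segment and Trdc, the 10 V segments with the highest mean share in WT and, of the remaining segments past an adjusted p of 0.05, the 10 with the largest change. Of the bins it takes the 5 with the largest change in each direction. The lists (Trdv, shared V, V without a settled name, Trdd, Trdj, Traj and other antigen receptor loci) were fixed at the same time. Of the other receptor loci, Trb and Trg were placed by read sequence, and Igh, Igk and Igl were not analysed here.

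Alternatives were collapsed repeats, all junctions as denominator, exclusion of 1000 bp around Trdd2, libraries sampled down, assignment within 10 or 200 bp, no filter or a minimum of 50 junctions, limma with trend on log2 junctions per 10000 plus a pseudocount of 1 or 10, median-centred scaling, a replicate block, 50 kb bins and each library left out. Trdj1 lies within 1000 bp of Trdd2, so the wider exclusion removes Trdj1 from the denominator. Sequencing run as a block and 10 kb bins in place of segments were chosen after seeing the data. A limit to uniquely mapped reads was not run, because mapping could not be redone and the lines of the other 11 libraries give no mapping flag.

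The fits were tested on simulated counts drawn from the libraries' own means and sizes, with a common spread per comparison in place of that of each feature. In 10 simulated tables per fold and comparison, 1 in 5 features were changed, up and down alike. False calls made up 0 to 13.3% of the calls. The real 5P comparison had 5 segments higher and 47 lower, and this false-call share does not cover changes that mostly go in the same direction. With a 2-fold change, 53.8% of changed segments were recovered in the 5P comparison (65 segments), 9.23% in the 3P comparison (67 segments), 16.2% between the baits in WT (67 segments) and 16.9% for the interaction (64 segments). With a 4-fold change these shares were 86.9%, 68.5%, 83.1% and 60.0%. For bins, 50.0% (5P, 31 bins) and 21.7% (3P, 32 bins) were recovered at 2-fold, and 83.3% and 75.0% at 4-fold. Replicates were compared by a chi-square test of their counts over segments. The closest pair, 5P WT replicates 1 and 3, had a chi-square of 77.4 over 52 degrees of freedom, 1.49 per degree, and the most distant pair 45.5 per degree. That test takes reads as independent, which repeats violate. With repeats collapsed the closest pair stood at 1.38 per degree, and it shared 57.3% of the collapsed lines of its smaller library, against 59.3% for 5P WT replicates 2 and 3, which stood at 4.10 per degree. The lowest shares of common lines were 0.218% and 0.429%, between 3P CBE KI replicate 3 and replicates 1 and 2 of its group. Its bait alignment ended at 54538511 in 99.4% of lines, 1 bp from the 54538510 of the other 3P libraries, and with that end left out these pairs shared 39.7% and 40.8%. Repeats were collapsed within each library, so this offset does not enter their count. The closest pair came from different sequencing runs and its members were kept as 2 replicates, but a common origin is not excluded. The fits without either of them are among the alternatives.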

Results

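The data describe how the Trdd2 diversity segment of the mouse Tcra-Tcrd locus was joined to other segments in early T cell precursors. The study asked whether 1 added CTCF binding element, placed beside the Tcrd enhancer, changes which V segments reach Trdd2 and how far the RAG recombinase acts along the locus. Trdd2 (chromosome 14, 54538431 to 54538446, mm9) has a recombination signal on either side. A join through the 5′ signal links it to an upstream V segment or to Trdd1, and a join through the 3′ signal links it to Trdj1, Trdj2 or a Traj segment further downstream. The 5P bait reads joins to upstream partners as the signal ends left on excised circles and joins to J segments as coding ends, and the 3P bait reads the reverse. The 12 libraries fall into 4 groups of 3, WT and CBE KI for either bait. Each library held between 8124 and 154495 deposited junctions, and 3P WT replicate 3 was the smallest. Between 0.0879% and 0.50% of them lay outside the locus. The share of locus junctions at a segment was 95.6% to 96.3% in WT and 94.8% to 96.2% in CBE KI with the 5P bait. With the 3P bait it was 93.2% to 94.7% in WT and 86.7% to 90.4% in CBE KI, with no overlap of the libraries.

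In unmodified cells most junctions of either bait lay at the same pair of neighbours, Trdj1 and Trdd1. Trdj1, the J segment nearest to Trdd2 (54539342), held 46.2% ± 2.04 of junctions with the 5P bait and 47.0% ± 4.09 with the 3P bait (SD, n = 3 each). Trdd1, the next diversity segment upstream (54529679 to 54529688), held 33.2% ± 0.142 and 27.6% ± 4.45, a log2 difference of 0.32 (SE 0.0817, limma adjusted p = 0.0206). Trdv5 (54558014), an inverted V segment downstream of the enhancer, held 3.09% ± 0.243 with the 5P bait against 1.40% ± 0.213 with the 3P bait, 2.36-fold higher (SE 0.155 on the log2 scale, limma adjusted p = 0.00364). Trdv1 was also higher with the 5P bait (log2 0.74, SE 0.175), and Trdj2 was lower (log2 -1.92, SE 0.382). Of 67 segments, 7 were higher and 11 were lower with the 5P bait (limma adjusted p under 0.05). The groups did not overlap at 25 segments, where chance gives 10%. Copies of the Trav15-dv6 family, V segments shared by both chains, were lower with the 5P bait, at log2 differences of -8.18 (SE 1.37, 54022856), -6.26 (SE 0.911, 53490913) and -5.23 (SE 0.797, 53919203), but these copies share reads. The copy at 53584921 had 341 junctions with the 3P bait and 1 with the 5P bait, a pooled ratio of 443 (counting interval 79.0 to 17555). Without single libraries that ratio was 273 (3P WT replicate 1), 1231 (3P WT replicate 2), 288 and 237 (5P WT replicates 1 and 2) or at least 120.3 (5P WT replicate 3). The V site at 54073014, without a settled name, was higher, with 700 against 12 junctions. These copies and this site were named for this comparison after their values were seen. Trdv2-2, Trdv2-1, Trdv4 and Trdj1 did not pass the test, with log2 differences of -0.06, -0.81, -0.54 and -0.06.

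The bait difference depended on how repeated reads were counted. Collapsing also limits the count of an abundant segment whose joins share few positions, and the baits read the same segment as different ends. The collapsed values therefore do not show that repeats of 1 molecule made the differences. With repeats collapsed the log2 difference was 2.19 for Trdj1, -0.89 for Trdv5 and -0.69 for Trdv1, and Trdv2-2 (log2 -1.26) and Trdv4 (log2 -1.25) were lower too, all past the threshold. The adjusted p over all alternatives ran from 0.000844 to 0.930 for Trdj1, 2.85e-05 to 0.0301 for Trdv5 and 0.00255 to 0.259 for Trdv1. It ran from 0.000810 to 0.995 for Trdv2-2, 0.00168 to 0.967 for Trdv4 and 0.000292 to 0.0701 for Trdj2. Leaving out 3P WT replicate 1 gave 42 segments, leaving out 3P WT replicate 2 gave 9, and sequencing run as a block gave 40. The calls of Trdv1 and Trdj2 were lost without 3P WT replicate 2 (adjusted p = 0.259 and 0.0643), and Trdv4 passed without it (log2 -1.09, adjusted p = 0.0345). That of Trdv1 was also lost without 5P WT replicate 2 or 3 (0.0742 and 0.0605), and that of Trdd1 without any 5P WT replicate or without 3P WT replicate 2 (0.0677 to 0.129, within a range of 0.00312 to 0.885 over all alternatives). Median-centred scaling gave 10 higher and 6 lower.

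With the 5P bait, Trdj1 made up a larger share of junctions in CBE KI than in WT, and Trdd1, Trdv5 and the Traj segments made up smaller shares. Trdj1 rose from 46.2% ± 2.04 to 67.6% ± 3.80 of junctions (SD, n = 3 each, log2 fold change 0.56, SE 0.0656, limma adjusted p = 3.31e-06). Trdd1 fell from 33.2% ± 0.142 to 16.9% ± 1.64 (log2 fold change -0.97, SE 0.0789, adjusted p = 1.74e-07), though without Trdj1 in the denominator it stood at -0.23 (adjusted p = 1.13e-06) and median-centred scaling put it at 0.43 (adjusted p = 0.0395, the highest of its alternatives, from 1.07e-20). Trdv5 fell from 3.09% ± 0.243 to 0.939% ± 0.170, 3.35-fold (SE 0.148 on the log2 scale, adjusted p = 1.74e-07). Of 65 segments tested, 5 rose and 47 fell, and the groups did not overlap at 47, where chance gives 10%.

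All 5 Trdv segments, which serve the T cell receptor delta chain, were lower in the 5P bait, and 5 passed when adjusted over the list alone. Trdv2-2 fell from 4.42% ± 0.429 to 1.92% ± 0.191 (log2 fold change -1.22, SE 0.127, adjusted p = 7.78e-07), and Trdv4, the V segment nearest upstream of Trdd1, fell from 0.490% ± 0.0852 to 0.191% ± 0.0189 (log2 fold change -1.38, SE 0.197). Trdv1 and Trdv2-1 fell as well, with log2 fold changes of -0.53 and -0.78 (limma adjusted p = 0.0103 and 0.0313). With Trdj1 taken out of the denominator, Trdv2-2 (log2 -0.48), Trdv4 (log2 -0.65) and Trdv5 (log2 -1.0) were lower, and Trdv1 stood at 0.22 without passing the test. Median-centred scaling, which moved the median of all segments from -1.38 to 0.061, turned the direction of this list. It put Trdv1 (log2 0.90) and Trdv2-1 (log2 0.70) higher and left Trdv5 at -0.33, with an adjusted p of 0.0836 that is the highest of its alternatives (from 2.64e-17).

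Traj segments are J segments of the alpha chain. The 30 of them that were called and named from reads all fell in the 5P bait. Their median log2 fold change was -3.55, the same with 2 segments set at their bounds. Their summed share was 0.943% ± 0.119 in WT and 0.105% ± 0.0424 in CBE KI (n = 3 each, exact permutation p = 0.10, the smallest possible). Traj42 fell from 0.107% ± 0.00675 to 0.00641% ± 0.00294, 17.0-fold (SE 0.359 on the log2 scale, limma adjusted p = 1.74e-07). Traj37 had 31 WT junctions and none in CBE KI, where 0 of 389467 junctions allows up to 0.000770%, and was at least 16.7-fold lower. Traj16 was at least 12.9-fold lower on the same footing. The pooled ratio of WT to CBE KI was 33.9 for Traj17 (counting interval 5.46 to 1403), 19.4 for Traj32 (6.12 to 98.4) and 40.4 for an unnamed J site at 54620755 (10.6 to 343). Without CBE KI replicate 3 the bounds were 10.6-fold for Traj37 and 8.20-fold for Traj16, and the ratios were at least 7.17 for Traj17 and 36.9 for Traj32. The log2 fold changes of Traj47, Traj18, Traj45 and Traj15 were -4.37, -4.31, -3.95 and -3.81. The fall of Traj35 (log2 -2.88, adjusted p = 0.0407) did not show in its pooled junctions, 51 in WT and 87 in CBE KI, since CBE KI replicate 3 held 0.0611% and the other CBE KI libraries held none; it was singled out after its values were seen. Of the 30, 28 fell without Trdj1 in the denominator, 26 with repeats collapsed, 25 with median-centred scaling and 28 with sequencing run as a random block. Trdj2 fell from 0.0291% ± 0.000577 to 0.0144% ± 0.00429 (log2 fold change -1.06, SE 0.322, limma adjusted p = 0.00868), and median-centred scaling put it at 0.44 (adjusted p = 0.237, from 0.00535 to 0.371 over its alternatives).

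Among 22 V sites without a settled name, 4 rose, 7 fell and 11 did not pass the test in the 5P bait (3 and 7 adjusted over the list alone). The most used of them, at 54403358 between Trdv2-2 and Trdv4, rose from 2.14% ± 0.0549 to 2.98% ± 0.497 (log2 fold change 0.45, SE 0.140, limma adjusted p = 0.00916). The site at 54309212 rose (log2 0.47), as did those at 54195446 (log2 0.68) and 54372670 (log2 0.47), the latter pair named after their values were seen. The site at 54188424 fell (log2 -0.45). Those at 54131138 and 54073014 stood at 0.31 and 0.19 and did not pass the test, although 54131138 did without WT replicate 2 (log2 0.44, adjusted p = 0.0454) or CBE KI replicate 3 (log2 0.43, adjusted p = 0.0306), with a highest value of 0.263 over its alternatives. Of 4 V segments shared by the alpha and delta chains, 2 fell, Trav21-dv12 (log2 -0.46) and the Trav15-dv6 copy at 53919203 (log2 -0.77, named after its values were seen), and none passed when adjusted over the list alone. None of this list passed with sequencing run as a random block or with repeats collapsed either. The direction of both V lists depended on the denominator, since without Trdj1 none of either fell and 13 of the unnamed sites rose, and median-centred scaling raised 16 unnamed and 3 shared segments.

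Several of the smaller 5P calls rested on single libraries. Without CBE KI replicate 1 the limma adjusted p was 0.0561 for Trdv1, 0.0569 for Trdv2-1, 0.149 for 54188424, 0.0813 for 54309212 and 0.123 for Trav21-dv12. The call of Trdv2-1 was also lost without WT replicate 1 (0.0650), WT replicate 3 (0.0794) or CBE KI replicate 3 (0.129), that of 54188424 without WT replicate 1 (0.0680), WT replicate 2 (0.146) or CBE KI replicate 3 (0.0534), that of 54309212 without WT replicate 1 (0.0601), WT replicate 3 (0.109) or CBE KI replicate 2 (0.0650), and that of Trav21-dv12 without WT replicate 2 (0.144), WT replicate 3 (0.134) or CBE KI replicate 3 (0.116). With repeats collapsed, Trdv1 (0.0959), Trdv2-1 (0.270), Trdj2 (0.145), 54188424 (0.0706) and Trav21-dv12 (0.483) did not pass. The adjusted p over all alternatives reached 0.0959 for Trdv1, 0.947 for Trdv2-1, 0.149 for 54188424, 0.109 for 54309212 and 0.483 for Trav21-dv12. Median-centred scaling gave 23 higher and 26 lower in place of 5 and 47.

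**Figure D1:**
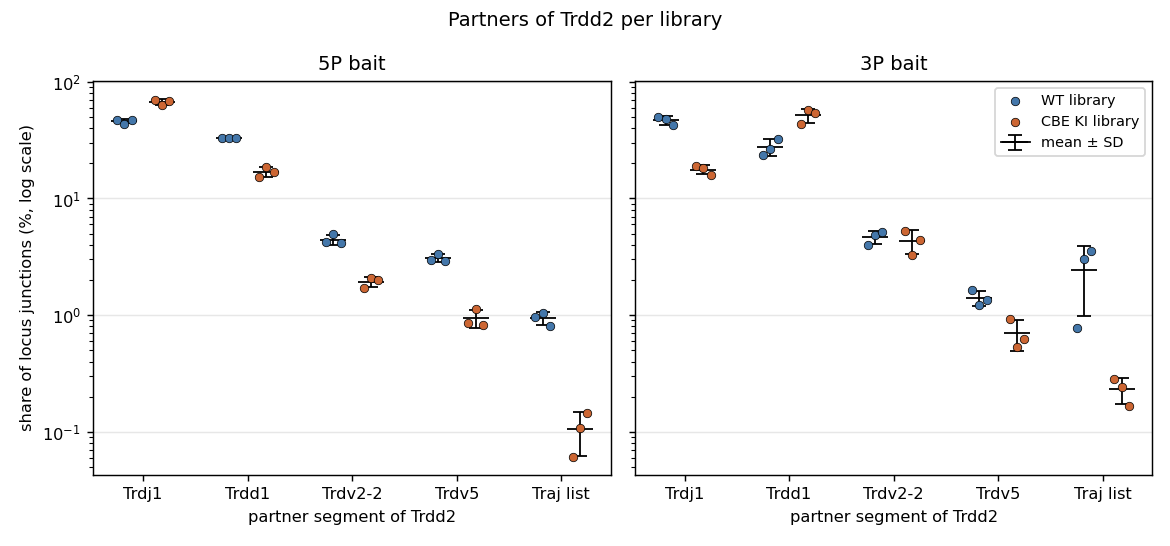
Share of locus junctions (percent, log scale) held by the named partners of Trdd2 in each library, for the 5P and the 3P bait, with points for single libraries and bars for the mean and SD of 3 libraries per group. Trdj1 lies higher and Trdd1 lower in CBE KI than in WT with the 5P bait and the reverse with the 3P bait, and Trdv5 lies lower in CBE KI with both baits; with median-centred scaling Trdd1 in the 5P bait and Trdv5 in the 3P bait lie higher in CBE KI.

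With the 3P bait, Trdd1 made up a larger share of junctions in CBE KI than in WT, and Trdj1 a smaller share. Trdd1 rose from 27.6% ± 4.45 to 51.6% ± 7.10 of junctions (SD, n = 3 each, log2 fold change 0.94, SE 0.152, limma adjusted p = 0.00313). Its call was lost with repeats collapsed (log2 0.21), without Trdj1 in the denominator (log2 0.27) and with sequencing run as a random block (log2 0.92). Trdj1 fell from 47.0% ± 4.09 to 17.7% ± 1.64 (log2 fold change -1.44, SE 0.130, adjusted p = 3.59e-05). The V site at 54403358 rose from 3.28% ± 0.537 to 6.43% ± 1.44 (log2 fold change 0.93, SE 0.228, adjusted p = 0.0175). Trdj2 fell from 0.109% ± 0.00702 to 0.0295% ± 0.0141 (log2 fold change -1.85, SE 0.533, adjusted p = 0.0327).

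Of 67 segments in the 3P bait, 2 rose and 16 fell, and the groups did not overlap at 26, where chance gives 10%. The Traj list held 14 of the falls, 17 when adjusted over the list alone, and all 30 members had a negative log2 fold change (median -2.76, the same with 2 segments at their bounds), but with sequencing run as a random block limma called 0 of them, and 8 had an unadjusted p under 0.05. Its summed share was 2.44% ± 1.46 in WT and 0.231% ± 0.0599 in CBE KI (n = 3 each, exact permutation p = 0.10, the smallest possible). Traj50 fell from 0.369% ± 0.194 to 0.0269% ± 0.0151, 14.5-fold (SE 0.677 on the log2 scale, limma adjusted p = 0.00376). The log2 fold changes of Traj49 and Traj40 were -3.52 and -3.65. Traj27 had 39 WT junctions and none in CBE KI, where 0 of 147895 junctions allows up to 0.00203%, and was at least 10.4-fold lower. Traj28, with 26 of its 28 WT junctions in WT replicate 2, was at least 7.44-fold lower, and at least 3.09-fold without that library. The pooled ratio of WT to CBE KI was 29.9 for Traj37 (counting interval 7.99 to 251), 27.9 for Traj6 (4.69 to 1133) and 17.8 for Traj35 (5.84 to 88.5). Without CBE KI replicate 1 or 3 the bounds were 5.03-fold and 6.82-fold for Traj27 and 3.61-fold and 4.90-fold for Traj28, and the ratio of Traj6 was 13.6 and 18.4. That of Traj6 was at least 7.96 without CBE KI replicate 2, and that of Traj37 was 13.9 without WT replicate 2. The log2 fold changes of Traj45 and Traj22 were -3.70 and -3.14.

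No Trdv segment passed the test in the 3P bait by limma-voom, over all segments or adjusted over the list alone. Trdv5 was at 1.40% ± 0.213 in WT and 0.697% ± 0.206 in CBE KI (log2 fold change -0.89, SE 0.323, limma adjusted p = 0.0611). Trdv2-2 was at 4.65% ± 0.592 and 4.34% ± 1.02, and the log2 fold changes of Trdv4, Trdv1 and Trdv2-1 were -0.28, 0.20 and 0.02. Trdv5 passed without WT replicate 1 (log2 -0.84, adjusted p = 0.0328), with repeats collapsed (log2 -1.06, adjusted p = 0.0151) and without Trdj1 in the denominator (log2 -1.56, adjusted p = 0.00717), while sequencing run as a random block gave -0.75 with the highest adjusted p of its alternatives, 0.482. Without Trdj1, Trdv2-2 fell as well (log2 -0.73, adjusted p = 0.0287, within a range of 0.00693 to 0.942), and median-centred scaling put Trdv2-2 at 1.18 and Trdv5 at 0.35. None of the 5 shared V segments passed (Trav15-dv6 copies at 53919203, 54022856 and 53490913 at 0.10, 0.94 and 0.50), except that the copy at 54022856 passed without WT replicate 1 (log2 1.65, adjusted p = 0.00175, up to 0.781 over its alternatives). Of 23 unnamed V sites the one at 54403358 alone passed, with those at 54131138 and 54188424 at 0.33 and 0.19; median-centred scaling raised 3 and 9 of these lists.

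The 3P calls rested on few libraries of uneven depth. The 18 calls became 41 without WT replicate 1, 7 without WT replicate 2, 4, 8 and 4 without CBE KI replicates 1, 2 and 3, and 1 (Trdj1, adjusted p = 0.00227) with sequencing run as a random block. Trdd1 did not pass with repeats collapsed (log2 0.21, adjusted p = 0.337, from 3.05e-05 over its alternatives), without Trdj1 in the denominator (log2 0.27, adjusted p = 0.147) or with sequencing run as a random block (log2 0.92, adjusted p = 0.0656), and Trdj1 did not pass with median-centred scaling (log2 -0.24, adjusted p = 0.358, from 5.55e-08). Trdj2 was lost without any 1 of WT replicates 2 and 3 and the CBE KI replicates (adjusted p = 0.0563 to 0.107, within 0.000879 to 0.357 over all alternatives), and 54403358 without WT replicate 2, CBE KI replicate 1 or CBE KI replicate 3 (0.0630, 0.0863 and 0.0618), with repeats collapsed (0.127) or without Trdj1 in the denominator (0.419), within a range of 0.000233 to 0.419. Traj27, Traj40 and Traj49 were lost without CBE KI replicate 1 (0.106, 0.0912 and 0.106) or 3 (0.107, 0.0663 and 0.0982), with highest values over all alternatives of 0.268, 0.111 and 0.106. Traj45, Traj37, Traj28, Traj6, Traj35 and Traj22 were lost without CBE KI replicates 1, 2 or 3 and in part without WT replicates 2 or 3 (0.0556 to 0.236, within a highest value of 0.324 over all alternatives). Median-centred scaling, which moved the median of all segments from -1.35 to -0.12, gave 15 higher and 5 lower in place of 2 and 16.

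**Figure D2:**
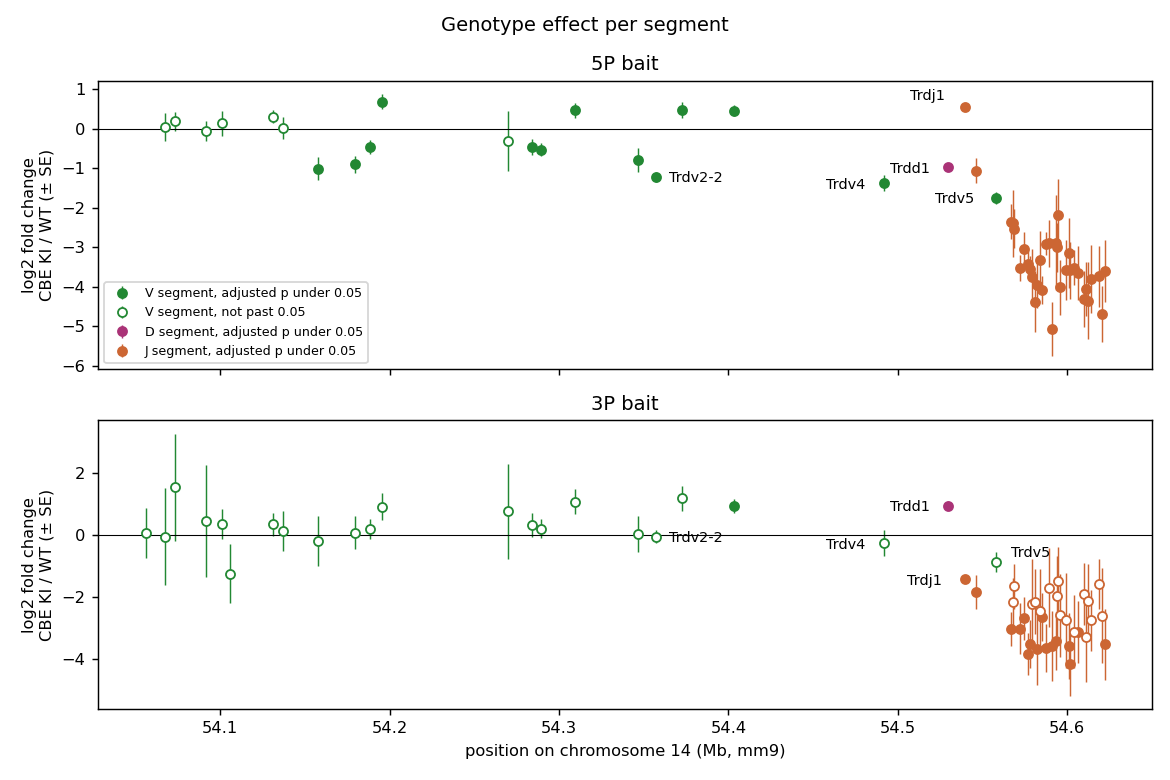
Log2 fold change of CBE KI over WT for each tested segment in the downstream part of the locus, by position (mm9), for the 5P and the 3P bait, with filled points for a limma adjusted p under 0.05 and bars for the standard error. The 30 named Traj segments lie below 0 with both baits and with every scaling tried, Trdj1 and Trdd1 lie on opposite sides of 0 in the 5P and the 3P bait (median-centred scaling puts Trdd1 above 0 in the 5P bait), and fitted values of segments without CBE KI junctions, such as Traj37 and Traj16 in the 5P bait, are no bounds.

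The genotype effect itself differed between the baits at 3 of 64 segments tested in all 12 libraries. For Trdj1 the effect in the 3P bait minus that in the 5P bait was -1.98 (log2, SE 0.139, limma adjusted p = 8.27e-09). For Trdd1 it was 1.89 (SE 0.165, adjusted p = 1.07e-07), and for Trdv2-2, which fell in the 5P bait and did not pass the test in the 3P bait, it was 1.15 (SE 0.244, adjusted p = 0.00489). Trdv5 (0.85, SE 0.308, adjusted p = 0.222) and the other Trdv and Trdj segments did not pass. With repeats collapsed Trdv2-2 did not pass (log2 0.48, adjusted p = 0.338). Without Trdj1 in the denominator Trdv2-2 stood at -0.25 (adjusted p = 0.566) and Trdj2 passed (log2 -2.17, adjusted p = 0.0392, up to 0.951 over its alternatives), and median-centred scaling left 1 call, Trdj1, which was lower, with an adjusted p of 0.242 for Trdd1 (from 1.48e-12) and 0.824 for Trdv2-2 (from 0.000591), the highest of their alternatives. Of 64 segments tested in both baits, 18 were called in both. Of these 15 fell in both, where independent lists would share 11.8, 1 rose in both (54403358), and Trdj1 and Trdd1 moved in opposite directions.

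Trdv5, which lies on the other side of the enhancer from Trdd2, was compared as a share with single-value tests. In the 5P bait it was at 3.09% ± 0.243 in WT and 0.939% ± 0.170 in CBE KI, 3.29-fold apart, and in the 3P bait at 1.40% ± 0.213 and 0.697% ± 0.206, 2.01-fold apart (n = 3 each, exact permutation p = 0.10 in either bait, the smallest possible). No WT library overlapped a CBE KI library in either bait. With labels permuted within each bait, the mean log2 ratio of CBE KI to WT was -1.36, 2.57-fold lower (exact permutation p = 0.005, the smallest possible). That test assumes that libraries of the baits vary independently, which the labels do not state. Sequencing runs put this in doubt, because WT replicates 2 of both baits shared a run, as did WT replicates 3. All CBE KI libraries shared a run that held no WT library, so run cannot be told apart from genotype here. With each library left out in turn the mean log2 ratio lay between -1.49 and -1.28, and with repeats collapsed at -0.92.

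Shares of whole regions followed their leading segments. The region from Trdd2 to Trdj2 held 46.5% ± 2.02 of 5P junctions in WT and 68.0% ± 3.78 in CBE KI, and 47.3% ± 4.12 and 17.9% ± 1.62 of 3P junctions. The region from Trdd1 to Trdd2 held 33.4% ± 0.157 and 17.2% ± 1.68 with the 5P bait and 27.9% ± 4.49 and 52.3% ± 6.95 with the 3P bait. Junctions downstream of Trdv5, where the Traj segments lie, made up 1.13% ± 0.158 and 0.163% ± 0.0424 with the 5P bait, 6.96-fold apart, and 3.04% ± 1.52 and 0.398% ± 0.0846 with the 3P bait, 7.64-fold apart. From Trdj2 to Trdv5 the shares were 3.13% ± 0.249 and 0.986% ± 0.166, and 1.60% ± 0.223 and 0.742% ± 0.231. The V region held 15.8% ± 1.59 and 13.7% ± 2.07 with the 5P bait (exact permutation p = 0.30, n = 3 each) and 20.2% ± 2.06 and 28.6% ± 6.12 with the 3P bait. All other exact permutation p-values of these region shares were 0.10, the smallest possible, with n = 3 each, and 0.125 (5P) and 0.10 (3P) after adjustment over the regions. Without Trdj1 in the denominator the V region difference turned, to 12.9 points higher in CBE KI in the 5P bait and -3.58 in the 3P bait.

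Junctions further than 50 bp from the border of any called segment were counted in 10 kb bins. The bins address how far along the chromosome joins to Trdd2 reach. Heptamers were read at called sites only, and whether off-segment junctions as a whole lie at recombination signals was not tested. Ends of segment joins trimmed by more than 50 bp would be among them, as would joins to V or J segments that were not called. Falls in bins downstream of Trdv5 may therefore include joins to uncalled Traj segments. The share of off-segment junctions was 5.34%, 6.18% and 6.81% in the 3P WT libraries and 13.3%, 9.59% and 10.4% in the 3P CBE KI libraries. With the 3P bait they rose in CBE KI in the consecutive bins from 54470001 to 54530000, which hold Trdv4 and Trdd1, and fell downstream of Trdj2. The bin at 54520001 to 54530000, which holds Trdd1, rose from 1.60% ± 0.142 to 4.01% ± 1.02 of locus junctions (SD, n = 3 each, log2 fold change 1.33, SE 0.219, limma adjusted p = 8.94e-05). The bins starting at 54480001, 54490001, 54500001 and 54510001 rose 2.27-fold, 2.44-fold, 1.98-fold and 2.32-fold, and that at 54470001, named after its values were seen, rose 1.92-fold. The bin at 54550001 to 54560000 fell from 0.103% ± 0.0307 to 0.00833% ± 0.0112, 17.5-fold in the limma fit (adjusted p = 0.000179), with a pooled ratio of 10.5 (counting interval 6.53 to 18.1). Further downstream, the bins at 54580001 and 54630001 had 60 and 48 WT junctions against 3 and 3 in CBE KI, pooled ratios of 15.9 (counting interval 5.20 to 79.5) and 12.8 (4.11 to 64.0). The ratio at 54630001 was 4.63 without WT replicate 2, 6.19 without CBE KI replicate 1 and at least 8.40 without CBE KI replicate 3. The bin at 54600001 fell 8.84-fold. That at 54590001 had no CBE KI junction, and its 13 WT junctions all lay in WT replicate 2, so it is given no fold. Of 32 bins, 6 rose and 7 fell, and the groups did not overlap at 8, where chance gives 10%.

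The call count of the 3P bins was 7 without WT replicate 2 and 7 without CBE KI replicate 1. Without WT replicate 2, the bins at 54490001, 54580001 and 54600001 no longer passed (limma adjusted p = 0.0760, 0.141 and 0.137). Without CBE KI replicate 1, those bins and the ones at 54590001 and 54630001 no longer passed (0.145, 0.0905, 0.200, 0.145 and 0.180). The bins at 54490001, 54590001 and 54630001 were also lost without CBE KI replicate 3 (0.123, 0.213 and 0.123), 54630001 without CBE KI replicate 2 (0.0961) and 54590001 without WT replicate 3 (0.124). The highest adjusted p over all alternatives was 0.430 for 54490001, 0.141 for 54580001, 0.570 for 54590001, 0.262 for 54600001 and 0.180 for 54630001. Without Trdj1 in the denominator 1 bin rose, that at 54520001, and 12 fell. The rises at 54490001, 54500001 and 54510001 were also lost with repeats collapsed (0.112, 0.0640 and 0.0795), with highest values over all alternatives of 0.430, 0.346 and 0.263.

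With the 5P bait, off-segment junctions fell in CBE KI in bins downstream of Trdv5. The bin at 54550001 to 54560000, most of which lies between Trdj2 and Trdv5, fell 3.03-fold (limma adjusted p = 0.00701, named after its values were seen), although the whole stretch from Trdj2 to Trdv5 held 1.10% of off-segment junctions in WT and 1.15% in CBE KI. That bin did not pass without CBE KI replicate 1 or 2 (adjusted p = 0.0670 and 0.0535), with repeats collapsed (0.0560), with libraries sampled down (0.162), with limma with trend at a pseudocount of 10 (0.0605) or without Trdj1 in the denominator (0.108), within a range of 0.00713 to 0.162 over its alternatives. The bin at 54580001 to 54590000 had 36 WT junctions and 2 in CBE KI, a pooled ratio of 29.1 (counting interval 7.48 to 249; log2 fold change -4.38, SE 0.951, limma adjusted p = 0.000320). The log2 fold changes of the bins at 54600001 and 54630001 were -3.51 and -2.72. That at 54590001 had no CBE KI junction and was at least 5.92-fold lower, and that at 54620001 had 3 CBE KI junctions and a pooled ratio of 10.2 (3.01 to 54.0). Without CBE KI replicate 3 these values were 18.4 (54580001), at least 3.76 (54590001) and 6.49 (54620001). The ratio at 54580001 was 16.1 without WT replicate 1 and at least 13.3 without CBE KI replicate 2, and that at 54620001 was 5.03 without WT replicate 2 and at least 6.95 without CBE KI replicate 1. The 1 bin that rose, at 54180001 to 54190000 in the V region, went from 0.0362% ± 0.0219 to 0.0734% ± 0.0107 (log2 fold change 1.03, SE 0.363, adjusted p = 0.0206). Of 31 bins, 1 rose and 10 fell. The falls included bins of the V region at 53900001, 53910001 and 54360001, named after their values were seen, none of which passed without Trdj1 in the denominator. The bin at 53900001 had 12 WT junctions and 2 in CBE KI, a pooled ratio of 9.69 (counting interval 2.16 to 89.2). The log2 fold changes at 53910001 and 54360001 were -1.96 and -1.27. In the 5P bins the groups did not overlap at 12, where chance gives 10%. The count was 7 without WT replicate 2, 7, 6 and 7 without CBE KI replicates 1, 2 and 3, and 7 higher and 8 lower with median-centred scaling. The rise at 54180001 was lost without WT replicate 3, CBE KI replicate 1 or CBE KI replicate 2 (adjusted p = 0.186, 0.0528 and 0.0535), the fall at 54600001 without WT replicate 2 (0.0557) and that at 54620001 without CBE KI replicate 2 or 3 (0.0535 and 0.0778), with highest values over all alternatives of 0.186, 0.111 and 0.144.

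**Figure D3:**
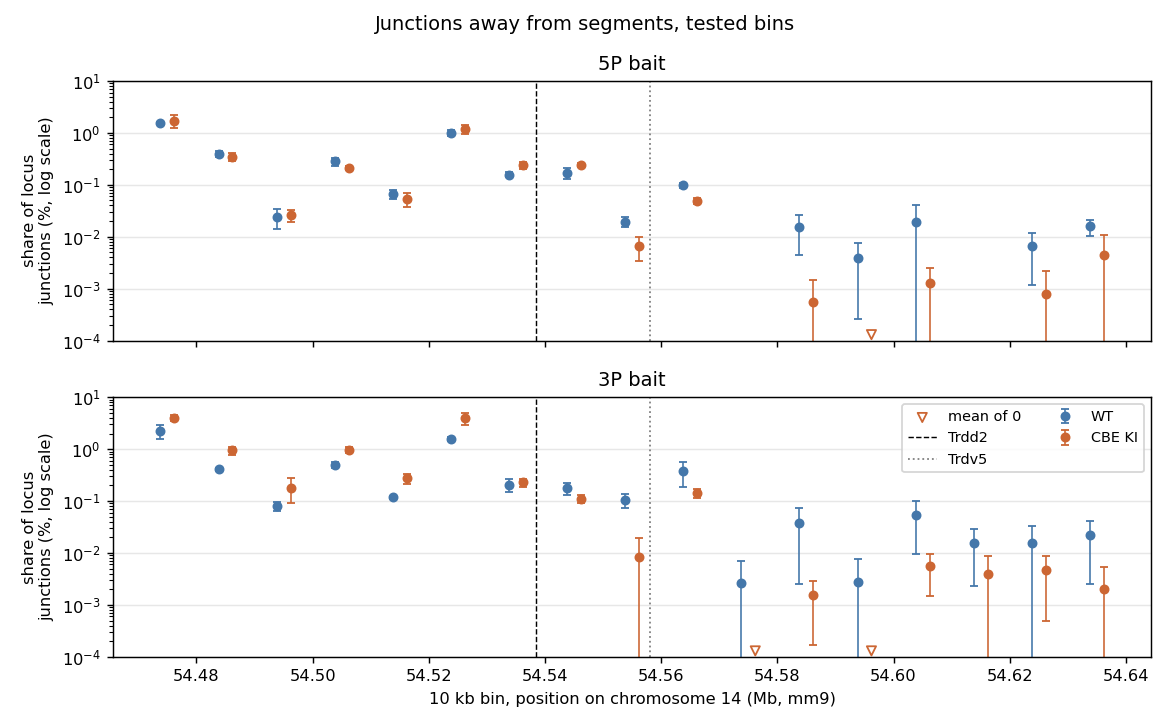
Share of locus junctions (percent, log scale) that lay away from called segments in each tested 10 kb bin from 54470001 on, by position (mm9), for the 5P and the 3P bait, with points for the mean of 3 libraries per group, bars for ± SD, clipped at the bottom of the axis, and open triangles for a mean of 0. CBE KI points lie below WT points at 54550001, 54560001 and from 54580001 on with both baits, and above them in the 3P bait from 54470001 to 54530000, an excess that passes the test in the bin at 54520001 alone once Trdj1 is left out of the denominator.

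Most off-segment junctions lay in the V region, and their share there was 83.2% ± 0.547 in WT and 82.3% ± 2.26 in CBE KI with the 5P bait, and 79.8% ± 4.45 and 90.2% ± 0.187 with the 3P bait. Downstream of Trdv5 the share of off-segment junctions was 4.2% ± 0.748 and 1.38% ± 0.232 with the 5P bait, and 9.05% ± 2.64 and 1.47% ± 0.0543 with the 3P bait. From Trdj2 to Trdv5 it was 1.10% ± 0.0931 and 1.15% ± 0.283 with the 5P bait, and 3.28% ± 1.27 and 0.384% ± 0.151 with the 3P bait, 8.54-fold apart. All off-segment junctions, the denominator here, were 5.34% to 6.81% of 3P locus junctions in WT and 9.59% to 13.3% in CBE KI. That larger denominator enlarges the 3P falls in these shares. Between Trdd1 and Trdd2 the share was 4.78% ± 0.240 and 5.30% ± 0.175, and 4.09% ± 0.650 and 6.39% ± 0.258. Between Trdd2 and Trdj2 it was 6.69% ± 0.778 and 9.83% ± 1.95, and 3.72% ± 1.10 and 1.54% ± 0.244. The exact permutation p was 0.10, the smallest possible with n = 3 each, except for the V region (0.60) and the stretch from Trdj2 to Trdv5 (0.80) in the 5P bait.

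Off-segment junctions lay mostly on the plus strand with the 5P bait. With the 3P bait they lay mostly on the minus strand, except between Trdd2 and Trdj2. The cause of this strand preference was not tested. In the V region 99.3% ± 0.256 of 5P junctions in WT and 99.1% ± 0.110 in CBE KI were on the plus strand, against 0.690% ± 0.228 and 0.50% ± 0.0829 of 3P junctions. Downstream of Trdv5 the plus-strand share was 99.3% ± 0.915 and 98.6% ± 1.41 with the 5P bait and 3.12% ± 2.39 and 0.889% ± 1.54 with the 3P bait. Between Trdd1 and Trdd2 it was 91.1% ± 2.25 and 90.6% ± 3.11, and 2.03% ± 1.83 and 0.769% ± 0.469, and from Trdj2 to Trdv5 92.5% ± 3.70 and 93.3% ± 4.17, and 2.10% ± 3.19 and 0.606% ± 1.05. The mixed stretch was that between Trdd2 and Trdj2, at 84.3% ± 2.47 and 90.1% ± 2.12 with the 5P bait and 38.8% ± 15.0 and 55.2% ± 12.7 with the 3P bait. Between WT and CBE KI the exact permutation p of the orientation share was 0.10, the smallest possible, from Trdd2 to Trdj2 with the 5P bait, where the libraries did not overlap, and 0.30 or more elsewhere (n = 3 each).

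The other lists gave the following summed shares in WT and CBE KI. The Trdv list was at 9.46% ± 0.839 and 4.08% ± 0.540 with the 5P bait and at 7.98% ± 0.573 and 6.72% ± 1.52 with the 3P bait. The shared V list was at 0.304% ± 0.0489 and 0.223% ± 0.0203, and at 2.45% ± 1.95 and 2.64% ± 0.917. The unnamed V list was at 5.83% ± 0.660 and 6.81% ± 0.967, and at 6.25% ± 1.28 and 9.96% ± 2.37. The Trdj list, Trdj1 and Trdj2, was at 46.3% ± 2.04 and 67.6% ± 3.79, and at 47.1% ± 4.09 and 17.7% ± 1.63, and the Trdd list held Trdd1 alone. Exact permutation p-values were 0.10 (the smallest possible, n = 3 each) except for the unnamed V list with the 5P bait (0.30), the Trdv list with the 3P bait (0.30) and the shared V list with the 3P bait (1.0), and none was below 0.16 after adjustment over the lists. Trb and Trg, the other T cell receptor loci open to RAG at this stage, held 130 and 158 junctions over the 12 libraries. Their shares did not differ detectably at this depth, with 0.00697% ± 0.000229 and 0.00682% ± 0.00260 for Trb and 0.00830% ± 0.00456 and 0.00511% ± 0.00359 for Trg in the 5P bait, and 0.0206% ± 0.0141 and 0.0147% ± 0.00953 for Trb and 0.0374% ± 0.0215 and 0.0158% ± 0.0122 for Trg in the 3P bait (exact permutation p = 0.30 or more, n = 3 each).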

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

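The tests below of the opposite changes of Trdj1 and Trdd1 were chosen after that result was seen, and the comparison with other splits of the libraries was not.

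The change from WT to CBE KI differed between the baits at 3 segments, by limma's interaction test over 12 libraries. For Trdj1 the change in the 3P bait minus that in the 5P bait was -1.98 (log2, SE 0.139, adjusted p = 8.27e-09). For Trdd1 the difference was 1.89 (SE 0.165, adjusted p = 1.07e-07). In either bait no WT library overlapped a CBE KI library for Trdj1 or Trdd1. For Trdv2-2 the difference was 1.15 (SE 0.244, adjusted p = 0.00489), with no overlap in the 5P bait and overlap in the 3P bait. Of 100 drawn splits of the libraries, 4, the real one included, gave at least as many calls as its 3. That share is under 0.05, but 1 more such split would have ended this. Mixing the labels within a bait also removes its genotype effect, so these splits stand for no genotype effect at all. They therefore cannot decide whether the difference between the baits arose by chance. The highest other split gave 32 calls, and the ones with 32, 14 and 8 calls kept the real 5P labels and mixed the labels of the 3P libraries. The other 9 drawn splits of that kind gave 0 to 2 calls, so the 5P labels alone do not account for the high counts, and what does was not tested.

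In both baits the segment read as a coding join rose in CBE KI and the segment read as a signal join on an excised circle fell. The changes of Trdd1 in part mirror the share of Trdj1, because without Trdj1 in the denominator Trdd1 stood at -0.23 in the 5P bait, still past the test, and at 0.27 in the 3P bait, where it did not pass the test, and its difference between the baits was 0.50 (adjusted p = 0.0392, within 1.48e-12 to 0.242 over its alternatives). A single change in the choice between Trdj1 and Trdd1, seen alike from both sides, would move the log2 ratio of Trdj1 to Trdd1 in the same direction in both baits. That ratio changed by 1.52 in the 5P bait and by -2.31 in the 3P bait. It restates the opposite changes of these segments, so its signs were known beforehand and add no separate evidence. Fewer circles for every deletional join alike, as the only change, are argued against. Deletional V segments fell less than Trdd1 in the 5P bait, by a median gap of 0.923 (log2 relative to Trdj1, SE 0.129 over segments). These segments come from the same libraries, so that SE does not measure the spread between libraries. A uniform loss beside a changed choice between V segments and Trdd1 stays open. Of 25 such segments 18 fell less than Trdd1, and 1, the V site at 54195446, stood at 0.13 against Trdj1 (named after its values were seen). The other 6 fell further, among them Trdv2-2 (log2 -1.77 against Trdj1) and Trdv4 (log2 -1.93), where Trdd1 stood at -1.53, so for those 6 a loss of circles stays open. Repeated reads of 1 molecule do not account for the change of Trdj1, since with repeats collapsed the interaction of Trdj1 was -1.61 (adjusted p = 0.00674, within 1.60e-13 to 0.0494 over its alternatives). For Trdd1 in the 3P bait they stay open, since collapsing them took its log2 fold change from 0.94 (SE 0.152) to 0.21 (SE 0.161) and ended the call through a smaller change at about the same spread, and collapsing also limits the count of an abundant segment, which was not tested apart. A loss of circles that varies by segment may contribute and stays open, as do the sequencing run, which separates the genotypes, and a genotype effect, none of which was tested apart.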

How the results depend on the processing

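The alternatives with sequencing run as a block and with 10 kb bins in place of segments were chosen after seeing the data, and the others were not. Among the values that answer a comparison, 583 alternative values kept their direction and side, or stayed within 1.5 times for a count, 31 moved and 25 reversed. For shares compared within a bait the exact permutation p cannot fall below 0.10. Those values could not change side, so only their direction was free to differ. Among single named segments and bins 1243 kept their direction and side, 179 lost it, 27 gained one, 31 moved without a call and 16 reversed. All 30 named Traj segments had a negative log2 fold change in both baits under each denominator tried and under median-centred scaling. Trdv5 as a share was lower in CBE KI in both baits under each alternative tried for it, and its fitted change in the 3P bait was above 0 under median-centred scaling alone. The smallest library of the 3P bait held 8124 junctions, and its dispersion between libraries was 0.108 against 0.0140 in the 5P bait, so depth and spread both limit the 3P calls, and their parts were not tested. A limit to uniquely mapped reads was not run. Unless stated, the cause was not tested.

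The count of called segments in the 5P bait was 32 with a minimum of 50 junctions, where fewer segments were tested, and 23 with 10 kb bins in place of segments. In the 3P bait it was 7 with libraries sampled down, which lowers the depth, 7 with limma with trend at a pseudocount of 10 and 1 with sequencing run as a random block. Between the baits in WT it was 10 with limma with trend at a pseudocount of 10 and 40 with sequencing run as a block. The interaction gave 1 call with median-centred scaling and 7 with 10 kb bins in place of segments. The 5P bins gave 4 with libraries sampled down, 7 with a minimum of 50 junctions, 5 and 1 with limma with trend at a pseudocount of 1 and 10, and 3 with 50 kb bins. The 3P bins gave 7 with libraries sampled down and 5 with 50 kb bins.

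With each library left out in turn, the count ran from 4 to 41 for 3P segments, 9 to 42 between the baits in WT, 6 to 9 for 5P bins and 7 to 16 for 3P bins. As CBE KI minus WT in percentage points, the off-segment share of the V region in the 5P bait ran from -1.99 to 0.262 (without CBE KI replicate 3), and that from Trdj2 to Trdv5 from -0.0808 (without CBE KI replicate 3) to 0.199. The plus-strand share in the 5P bait ran from -2.03 to 1.07 between Trdd1 and Trdd2 (without CBE KI replicate 2, and 0.551 without WT replicate 2), from -1.56 (without CBE KI replicate 2) to 2.19 from Trdj2 to Trdv5, and from -1.38 to 0.0328 downstream of Trdv5 (without CBE KI replicate 2). From Trdj2 to Trdv5 in the 3P bait it ran from -2.55 to 0.339 (without WT replicate 1). The shared V list in the 3P bait ran from -0.550 (without WT replicate 3) to 1.30, Trb in the 5P bait from -0.00130 to 0.00126 (without CBE KI replicate 1) and Trb in the 3P bait from -0.0104 to 0.00225 (without WT replicate 2).

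Median-centred scaling reversed 5P log2 fold changes, to 0.90 for Trdv1, 0.70 for Trdv2-1, 0.20 for Trdv2-2, 0.061 for Trdv4, 0.43 for Trdd1, 0.44 for Trdj2, 0.99 for the V site at 54188424 and 0.99 for Trav21-dv12, and put Trdv2-2 in the 3P bait at 1.18. It sets the median segment near 0 by construction. Exclusion of 1000 bp around Trdd2, which takes Trdj1 out of the denominator, put Trdv1 at 0.22, the V site at 54188424 at 0.29 and Trav21-dv12 at 0.29 in the 5P bait and the interaction of Trdv2-2 at -0.25. It put the V region at 12.9 points (5P) and -3.58 (3P), the shared V list at 0.128 (5P) and -1.59 (3P) and the Trdj list at -0.0103 (5P). With repeats collapsed the difference between the baits in WT was -0.69 for Trdv1, 2.19 for Trdj1 and -0.89 for Trdv5 (log2), and the 5P changes were 0.680 points for the V region and 0.0103 for Trb. With libraries sampled down the plus-strand share changed by 1.12 points between Trdd1 and Trdd2 (5P), -3.09 (5P) and 0 (3P) from Trdj2 to Trdv5, and the off-segment share from Trdj2 to Trdv5 (5P) by -0.0359.

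Replicate numbers were not taken to pair the libraries, but a pairing is not excluded. In WT, replicates 2 of both baits shared a sequencing run, as did replicates 3, so across the baits these numbers go with run. The deviations of libraries with the same number correlated at 0.0707, -0.134 and -0.451 in the 5P bait and 0.0750, 0.447 and -0.313 in the 3P bait over segments, WT against CBE KI. Across the baits libraries with the same number correlated at 0.140, -0.0827 and 0.0575 in WT and at -0.134, 0.287 and 0.0820 in CBE KI, and in no such set did every library correlate best with its own number. With the replicate block the counts were 51 (5P segments), 14 (3P segments), 10 (baits in WT), 3 (interaction), 11 (5P bins) and 15 (3P bins).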

Other observations

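The tests of the Traj fall against the share of Trdj1 and against sequencing run, and that of a deletion of 5000 bp or more, were chosen after the result was seen, and those with repeats collapsed, of a deletion of at least 1000 bp and of other splits were not.

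Junctions downstream of Trdj2, the Traj segments among them, made up a smaller share in CBE KI in both baits. The altered share of Trdj1 does not account for it, because without Trdj1 in the denominator the Traj list was 5.41-fold lower in the 5P bait and 16.0-fold lower in the 3P bait. Repeated reads do not account for it, because with repeats collapsed the list was 6.93-fold and 8.09-fold lower (exact permutation p = 0.10 in either bait, the smallest possible, n = 3 each). Sequencing run cannot be told apart from genotype, since no run held both; with run as a random block 28 Traj segments were called in the 5P bait and 0 in the 3P bait by limma, where 8 Traj segments passed an unadjusted p of 0.05. A genotype effect stays open beside run, and libraries of both genotypes on 1 run would be needed to separate them. In the 3P bait joins to Traj segments and to Trdj1 are both read as signal ends on excised circles. As shares of locus junctions the Traj list was 10.6-fold lower there and the Trdj list 2.65-fold lower. Without Trdj1 the 3P denominator consists mainly of upstream joins, which enlarges the 16.0-fold value. A loss of circles may contribute to the 3P fall of the Traj list and was not tested. In the 5P bait, where J segments are read as coding ends, the Traj list was 9.01-fold lower.

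The genotype tag of the CBE KI libraries names a knockout in place of the knock-in of their titles. If those libraries carried a deletion between Trdv4 and Trdd1, a stretch of at least 1000 bp there would hold 10 or more WT junctions and no CBE KI junction. The interval held 46510 WT and 55977 CBE KI junctions, and 5 stretches of at least 1000 bp, the longest 1893 bp, had no CBE KI junction. At most 2 WT junctions lay in any of them, so a deletion inside one of them could not have shown the 10 WT junctions, and that test decides nothing about it. Every window of 5000 bp in the interval held at least 71 CBE KI junctions and junctions of all 6 CBE KI libraries, which argues against a deletion of 5000 bp or more there on every allele. A deletion on every allele of between 1893 and 5000 bp would need the CBE KI junctions inside it to be misplaced reads, and since windows of 2000 bp held as few as 2 of them this was not excluded. A shorter deletion, one on part of the alleles and one elsewhere stay open.

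Every comparison of 3 libraries against 3 has 10 splits, too few for a share under 0.05. In each of them 1 of the 10 splits, the real one, gave as many calls. The real split gave 52 segments in the 5P bait, 18 in the 3P bait and 18 between the baits in WT, and the highest other split gave 0 in each. For bins the real split gave 11 in the 5P bait, with 0 as the highest other, and 13 in the 3P bait, with 1 as the highest other.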
